A study of Gossypium hirsutum with 6 samples.

How the data were processed

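Total RNA from cotton leaves was labelled with biotin and hybridised to Affymetrix cotton arrays, 1 array per sample, for 3 control and 3 drought samples. The sample labels give each sample's group and replicate number. The labels call the 3 arrays of a group biological replicates; they do not say which of the 6 plots of each arm a sample came from, so p-values measure the spread between these samples. The deposited table holds log2 values made by the authors with RMA, per the submitters' processing notes, which name no more than RMA; its version is not given in the sources used here. The scale is not stated in the table; log2 is taken from RMA, whose output it is, and from the range of the values. In the deposited log2 values every probe set has a median of 0 over these 6 arrays (largest absolute median 5e-07), so they were centred per probe set before deposit and hold no absolute level; how the centring was made is not given in the sources used here. The direction is read as higher value for more signal, as RMA gives it, which the table itself does not state. Over the tested probe sets the column medians were -0.0472, -0.0459 and -0.0367 in control replicates 1, 2 and 3, and 0.0817, 0.0294 and 0.0459 in drought replicates 1, 2 and 3. Because of the centring, arrays of different groups correlate negatively (Pearson r from -0.945 to -0.935 across probe sets) and arrays of a group positively (0.913 to 0.944), which describes the centring and the group difference together. No value was missing and no ID was repeated.

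The table has 24132 probe sets, of which 103 are Affymetrix control probe sets that were kept out of the tests and reported apart: 27 hybridisation spike-ins, 42 poly-A spike-ins, 17 cotton quality control and 17 tag probe sets. The 52 reporter probe sets stayed among the 24029 tested. The platform's gene table pairs 697 probe sets with 1 gene and 46 with several, and 23286 tested probe sets have no gene in it; no gene is named from a probe set with several. All 697 were found in the RefSeq gene table of assembly Gossypium_hirsutum_v2.1, which was used for names only, and stand for 520 genes. All symbols are locus numbers, and 246 genes (324 probe sets) also have an older name, which is the name used here. No genome build is named for the array, so no positions are given.

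Drought was compared with control with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the deposited values, without a block, over all 6 arrays, with two-sided p-values adjusted by Benjamini-Hochberg over the 24029 probe sets and a threshold of 0.05. Every adjusted p for a gene and every SE is from that limma fit, with n = 3 arrays per group. Probe sets were counted in all, per direction, and with a difference of at least 1 log2 unit (2-fold). On simulated arrays with the residual spread of the real ones and 24029 probe sets, the fit recovered 0%, 42%, 82% and 100% of 50 probe sets changed by 0.25, 0.5, 1 and 2 log2 units, with 2 false calls among 114 (1.75%). Few simulated probe sets were changed, against 55.7% called in the real fit, so the adjusted threshold was stricter in the simulation. Its noise was independent, with no offset shared within an array. These rates therefore do not carry over to the real fit, where some differences under 0.25 passed.

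Gene lists were tested with camera of limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, against the other named genes, with Benjamini-Hochberg adjustment over the lists; fry of limma was run beside it. Lists under 5 genes have values and no test. The 21 text patterns fixed before the data were examined were written for gene descriptions, which the tables used here do not hold; 15 matched no gene and only 1 matched at least 5. For this reason 22 lists were drawn up from the older gene names after the annotation had been seen and array summaries and control probe sets had been looked at, and before any named gene's values were. They hold 175 of the 246 genes, and 17 have at least 5. The lists cover LEA and maturation proteins; salt, drought and calcium signalling; NAC; AP2/ERF, CBF, WRKY and homeobox; and MYB transcription factors; antioxidant enzymes; class III peroxidases; ethylene synthesis; fasciclin-like arabinogalactan proteins; cell wall enzymes; the cytoskeleton; fatty acid, wax and sterol enzymes; phenylpropanoid and flavonoid enzymes; sucrose synthases; MAP kinases; auxin; gibberellin and brassinosteroid; translation; Rubisco activase; and markers of fibre, flower and seed. The plan was to take the probe set with the highest mean for each gene, but centred values have no mean level. A rule that uses no value took its place: sense before antisense design, then IDs without a shared-probe suffix (_at, then _a_at, _s_at and _x_at), then ID order.

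The genes named in the text follow a rule fixed before the data were examined. They are the 10 named genes with the largest increase and the 10 with the largest decrease among those that passed with non-overlapping arrays, taking a gene's most changed probe set; the 2 genes with the smallest p in each list, or 4 where the list passed camera; and control probe sets. The rule's part on lists was written for the preset lists and was carried over to the lists from names when those were added. Other genes in the text are members of a list, or of a short count, or are named near the end as outside the lists. All of these were chosen after their values were seen.

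Alternatives chosen before the data were examined were centring each array on its median, quantile normalization, robust eBayes, array weights, the replicate number as a block, leaving out each array, probe sets designed on Gossypium hirsutum only, no probe sets with shared probes, thresholds of 0.01 and 0.1, limma's treat against a 1.2-fold difference, 1 probe set per gene, all probe sets of a list's genes and the estimated correlation. Centring on reporter probe sets, centring on hybridisation spike-ins, sense-design probe sets only, a camera background of all probe sets and the lists from names were chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.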

Results

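Leaf RNA of upland cotton (Gossypium hirsutum, cultivar Bikaneri Nerma) was measured on 6 Affymetrix cotton arrays. Of these, 3 came from control plants and 3 from plants from which water was withheld from peak flowering. The drought plants were sampled after 18 to 19 days without irrigation, when soil moisture was 19.5%, or 50% of that in the control plots. Each arm had 6 plots, and the labels call the arrays of an arm biological replicates. Each array reports 24132 probe sets, of which 24029 remained after removal of 103 Affymetrix control probe sets. The precision of every value below is limited by the number of arrays, 3 per group.

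The comparison asks which leaf transcripts differ between droughted and control plants. In drought leaves, transcripts of the NAC transcription factor gene NAC5, the late embryogenesis abundant (LEA) gene Lea5-D and the mitochondrial alternative oxidase gene AOX1 were many-fold higher. NAC5 rose by 5.53 on the log2 scale (SE 0.18, 46.3-fold, limma adjusted p = 3.04e-08). Lea5-D rose by 4.29 (SE 0.07, 19.5-fold, adjusted p = 1.34e-09) and AOX1, on an antisense-design probe set, by 4.22 (SE 0.07, 18.6-fold, adjusted p = 1.34e-09). CPA-FAS-2, a cyclopropane fatty acid synthase, fell by 7.40 (SE 0.15, 168-fold, adjusted p = 2.47e-09). The probe set of EXPA1, an expansin that loosens cell walls, fell by 4.78 (SE 0.11, 27.6-fold, adjusted p = 4.62e-09). That probe set lies in the same sequence cluster of the array as that of the sucrose synthase gene susC, so its value is not shown to belong to EXPA1.

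Over all tested probe sets, 13380 passed an adjusted p of 0.05, which is 55.7%; 8485 were higher and 4895 lower in drought. At least 2-fold differences were found for 1593 higher and 2074 lower probe sets as deposited, 1808 and 1996 after quantile normalization, and 1048 and 2533 with arrays centred on the hybridisation spike-ins. The balance turned with size: 392 were higher and 1072 lower by at least 4-fold, 35 higher and 269 lower by at least 16-fold, and 1 higher and 46 lower by at least 64-fold. Drought arrays lay wholly above control arrays for 9636 probe sets (40.1%) and wholly below for 5444 (22.7%), where chance gives 5% in each direction. The median log2 difference over all tested probe sets was 0.12, so small increases should be read against that shift. The share of called probe sets that were higher was 63.4% as deposited and 35.5% with arrays centred on the hybridisation spike-ins. It was 53.1% with each array centred on its median and 50.9% after quantile normalization. Because of the centring per probe set, control columns are close to mirror images of drought columns. Quantile normalization then evens out the shares and the 2-fold counts by construction, and median centring makes the array medians equal. These 2 settings therefore give no evidence on the balance of directions. Of the 52 reporter probe sets, designed on sequences foreign to cotton, 9 passed (17.3%), with a median of 0.09 and none reaching 1 log2 unit, so calls below 2-fold include differences of a size seen without a cotton target.

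Among 246 genes with a name, 78 were higher, 104 lower and 64 did not pass; 23 were higher and 55 lower by at least 2-fold. Besides NAC5, Lea5-D and AOX1, the largest increases were those of Pat1 (2.98, SE 0.10), NAC4 (2.83, SE 0.09), the ACC oxidase genes ACO1 (LOC107954048; 2.57, SE 0.09) and ACO1 (LOC107905899; 2.54, SE 0.07), the xyloglucan-modifying enzyme XTH3 (2.45, SE 0.09), the peroxidase pod7 (2.32, SE 0.14) and MYB1 (1.97, SE 0.08). After CPA-FAS-2, the largest decreases were those of PGIPL (-6.70, SE 0.16), the bHLH transcription factor GHDEL61 (-5.19, SE 0.22), the fasciclin-like arabinogalactan proteins FLA6 (-4.86, SE 0.11) and FLA13 (-4.75, SE 0.15), the sucrose synthase susC (-4.84, SE 0.07), EXPA1, H6L (-4.75, SE 0.11), CMDR1 (-4.73, SE 0.09) and XTH1 (-4.69, SE 0.11). Adjusted p-values of these 20 genes in limma ran from 6.77e-10 for susC to 1.19e-06 for pod7; they were taken from genes whose arrays did not overlap between groups.

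**Figure D1:**
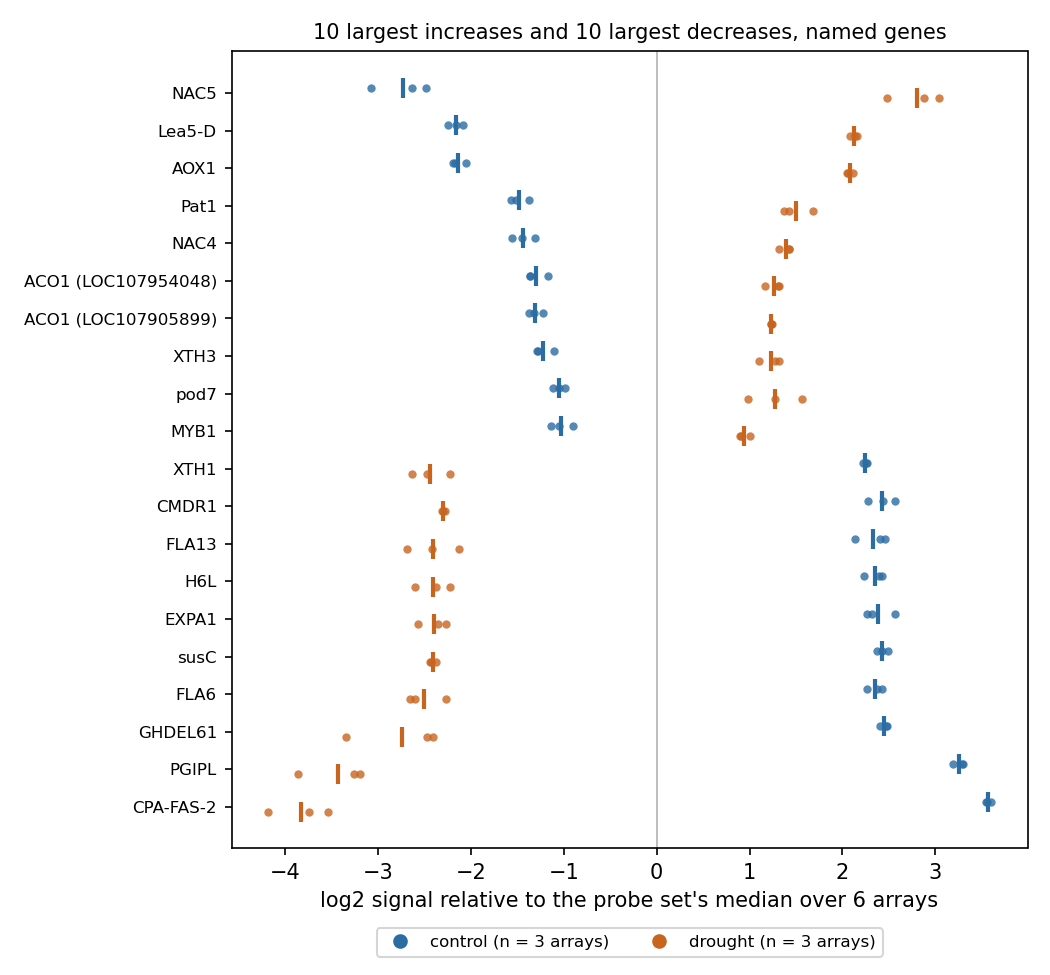
Log2 signal of the 10 named genes with the largest increase and the 10 with the largest decrease, relative to each probe set's median over the 6 arrays (x axis); points are single arrays, 3 control and 3 drought per gene, and ticks are group means. For NAC5 the drought mean was 2.80 and the control mean -2.73, and for CPA-FAS-2 the drought mean was -3.83 and the control mean 3.57.

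A list of NAC, WRKY, AP2/ERF and HD-Zip patterns fixed before the data were examined matched 7 genes, all of them ERF, DREB or WRKY genes, and all 7 rose on the probe set used, also when adjusted over the list alone; the other probe set of ERF9 (0.26) gave -0.000296 and did not pass. Their median was 0.66 (camera p = 0.00227, and p = 0.0338 with an estimated correlation). The list passed camera in all 10 splits of the 6 arrays into 3 and 3, so the call does not single out the drought grouping. Every split other than the real one keeps part of the group difference, so this does not count against drought either. ERF7 rose by 1.86, ERF8 by 1.01, DREB1C, of a family that binds the dehydration-responsive promoter element, by 0.96, and WRKY24 by 0.66. In a wider list of 13 AP2/ERF, CBF, WRKY and homeobox genes, 10 rose, 1 fell and 2 did not pass (camera adjusted p = 0.0117). Its call was lost with the estimated correlation (adjusted p = 0.26 with an estimated correlation). RAV1 rose by 1.49 and DBP2 by 0.98, the homeobox gene HOX3 fell by 1.82, and CBF17 (0.15) and DBP3b (0.32) did not pass, although another CBF17 probe set rose by 0.38. With arrays centred on the hybridisation spike-ins, 4 of the 7 and 7 of the 13 genes remained higher at the threshold.

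Of 7 NAC genes 3 rose, 1 fell and 3 did not pass, and the list did not pass camera (adjusted p = 0.114). NAC2 rose by 1.83 beside NAC5 and NAC4, and NAC7 fell by 1.83 on the probe set used, while its other probe set rose by 0.78. Of 4 LEA and seed maturation genes, Lea5-D and Lea14-A (0.99) rose, and MatP7 (-0.20) and Mat5-D (0.21) did not pass. Of 5 ethylene synthesis genes 4 rose and 1 fell, with a median of 0.79 (camera adjusted p = 0.0697); ACS1, an ACC synthase, rose by 0.79 and ACS3 fell by 1.17. ACO3 (0.20) turned to -0.05 with arrays centred on the hybridisation spike-ins. Of 8 salt, drought and calcium signalling genes 5 rose, none fell and 3 did not pass, with a median of 0.42 (camera adjusted p = 0.0697). The vacuolar sodium-proton exchanger NHX1 rose by 1.37 and the drought-induced zinc finger gene Di19-1 by 0.87; Di19-2 (0.19) turned to -0.06 with the spike-in centring. Of 5 MAP kinase genes 4 rose, MAPKKK by 1.26 and MPK14 by 0.72, and 1 did not pass (median 0.59, camera adjusted p = 0.0697). A preset aquaporin pattern matched 1 gene, which rose by 0.93, and Rubisco activase RCA1, the only photosynthesis gene in the lists, rose by 0.60.

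Of 12 genes for fasciclin-like arabinogalactan proteins (FLA), cell surface glycoproteins, 9 fell and 3 did not pass, with a median of -2.73 (camera adjusted p = 0.0174). This call was also lost with the estimated correlation (adjusted p = 0.26 with an estimated correlation). The decreases included those of FLA4 (-4.53), FLA15 (-4.37), FLA7 (-3.43) and FLA11 (-3.02). Among 18 expansin, XTH and other cell wall enzyme genes 12 fell, 3 rose and 3 did not pass (median -0.73, camera adjusted p = 0.0697). The chitinase-like gene CTL1 (-4.34), the cellulose synthase gene CesA1 (-3.97) and the expansin EXPA11A (-3.96) were among those that fell, and XTH3 among those that rose. The other probe set of CesA1 gave 0.26 and did not pass. With arrays centred on the hybridisation spike-ins 1 of the 18 was higher and 13 lower, and PG (0.25) was near 0. All 3 genes matched by the preset cell wall pattern, EXPA1, EXPA11A and EXPA4, fell. All 6 phenylpropanoid and flavonoid enzyme genes fell, with a median of -1.20 (camera adjusted p = 0.0697), among them DFR, dihydroflavonol reductase (-3.90), and CHS3, a chalcone synthase (-3.46). Of 17 cytoskeleton genes 11 fell, 1 rose and 5 did not pass (median -0.38, camera adjusted p = 0.0697). The alpha-tubulin genes TubA2 (-2.20) and TUA6 (-2.01) fell. Of 16 fatty acid, wax and sterol enzyme genes 9 fell, 2 rose and 5 did not pass (median -0.65, camera adjusted p = 0.184), and the stearoyl-ACP desaturase sad1 fell by 1.84; with the spike-in centring 0 were higher and 11 lower. Of 3 sucrose synthases, susC and Sus1 (-1.93) fell and SusA1 (0.77) rose. Of 7 translation genes 4 fell and 3 did not pass (median -0.20, camera adjusted p = 0.396), and RPL37A (-0.61) and EF1A7 (-0.56) were among those that fell, although another EF1A7 probe set rose by 0.21.

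Other lists were split. Of 10 antioxidant enzyme genes 6 rose, 3 fell and 1 did not pass (median 0.25, camera adjusted p = 0.324). Beside AOX1, a glutathione S-transferase gene, GST (LOC107948407), fell by 2.14. Only 1 of the 10 remained higher at the threshold with arrays centred on the hybridisation spike-ins, where Mn-SOD (0.24) turned to -0.00492. Of 10 class III peroxidases 4 rose, pod7 and pod1 (1.68) among them, and 5 fell, POX10 (-2.88) among them; the median was -0.44 and the mean -0.20 while camera gave the direction as up (adjusted p = 0.857). Of 10 MYB genes and partners 3 rose and 4 fell, GHMYB36 (-4.07) and GHDEL61 among them, with a median of -0.07 and a camera direction of up (adjusted p = 0.857). Of 4 auxin-regulated genes Aux2 (0.59) and Aux4 (0.46) rose and Aux3 (-0.66) and Aux6 (-0.45) fell. Of 5 gibberellin and brassinosteroid genes 2 rose, the gibberellin receptor gene GID1-2 by 1.76, and 1 fell, the DELLA gene GAI2 (-0.81), with 2 not passing (median 0.03, camera adjusted p = 0.649). With each array centred on its median, after quantile normalization, and with reporter or spike-in centring, 1 of the 5 was higher and 2 were lower. Adjusted over the list alone, 2 of those 5 genes fell, 13 of the 18 cell wall genes and 12 of the 17 cytoskeleton genes fell, and the counts of all other lists were as given.

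**Figure D2:**
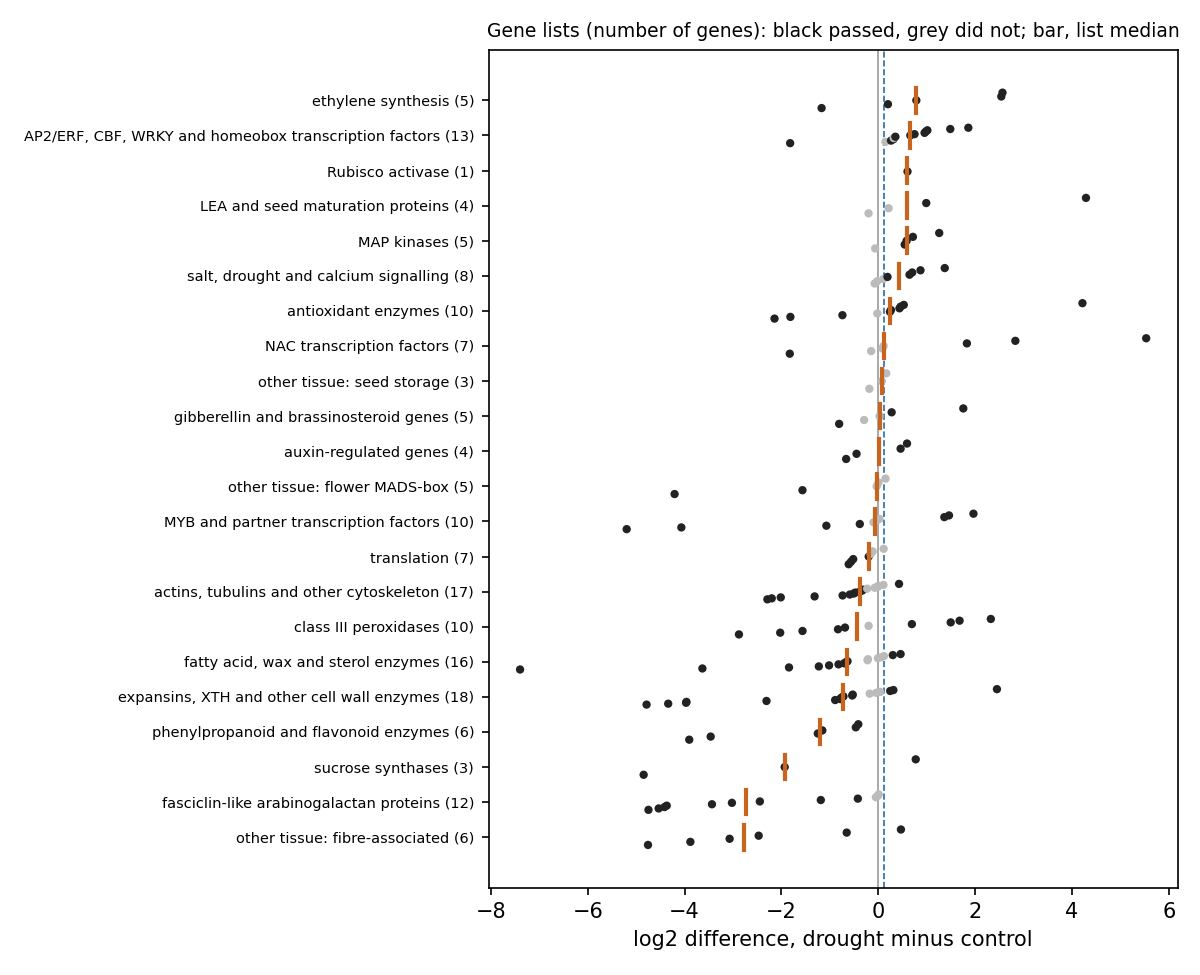
Log2 difference, drought minus control, of each gene in the 22 lists of named genes (x axis), with the number of genes in brackets; black points passed an adjusted p of 0.05 in limma, grey points did not, bars are list medians and the dashed line is the median of all probe sets, 0.12. List medians run from -2.77 for fibre-associated genes to 0.79 for ethylene synthesis genes.

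Markers of other cotton tissues gave mixed results. Of 6 fibre-associated genes 5 fell and 1, Fb2 (0.47), rose, with a median of -2.77 (camera adjusted p = 0.0697). H6L (-4.75), Ghfe1 (-3.88) and E6, an abundant fibre transcript (-3.07), were among those that fell. With the spike-in centring, Fb2 and the cytoskeleton gene that rose no longer passed as higher. Of 5 flower MADS-box genes MADS-1 (-4.21) and SEPALLATA3 (-1.56) fell, and 3 did not pass (median -0.03, camera adjusted p = 0.627). Of 3 seed storage genes none passed, with values of -0.18 for vicB_At and 0.16 for LEGB (median 0.07); vicB_At passed with a value of -0.28 when each array was centred on its median. None of the 17 tested lists from gene names passed with an estimated correlation, and the lists with a camera adjusted p of 0.0697 had adjusted p-values from 0.463 to 0.525 with an estimated correlation. Fry tests a list by itself and not against other genes. All tested lists from names passed it except class III peroxidases (fry adjusted p = 0.207) and MYB genes and partners (fry adjusted p = 0.139).

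Control probe sets also differed between the groups. The array median of 27 hybridisation spike-in probe sets was higher in drought by 0.247, and all 3 drought arrays lay above all 3 control arrays. That of 42 poly-A spike-in probe sets was higher by 0.224, and that of the 52 reporter probe sets by 0.0557. The hybridisation spike-ins did not share 1 offset. Their cre probe sets differed by 0.003 to 0.147, and their bioB, bioC and bioD probe sets by 0.155 to 0.437. Their closest array medians were 0.0116 in drought replicate 3 and -0.0123 in control replicate 2. For the quality control probe sets of upland cotton actin the 3' minus 5' difference changed by -0.57, for ubiquitin by -0.24 and for sucrose synthase by -1.83, where the 3' probe set fell by 2.12. For the probe sets of the same genes from Gossypium raimondii the changes were 0.64, 0.06 and 0.03. The 3', middle and 5' actin probe sets from Gossypium raimondii themselves rose by 1.83, 1.79 and 1.19. Those of upland cotton actin gave -0.21, -0.08 and 0.37 in the same order. Upland cotton ubiquitin rose by 0.55 on the 3' and 0.79 on the 5' probe set, and the middle sucrose synthase probe set fell by 1.73.

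**Figure D3:**
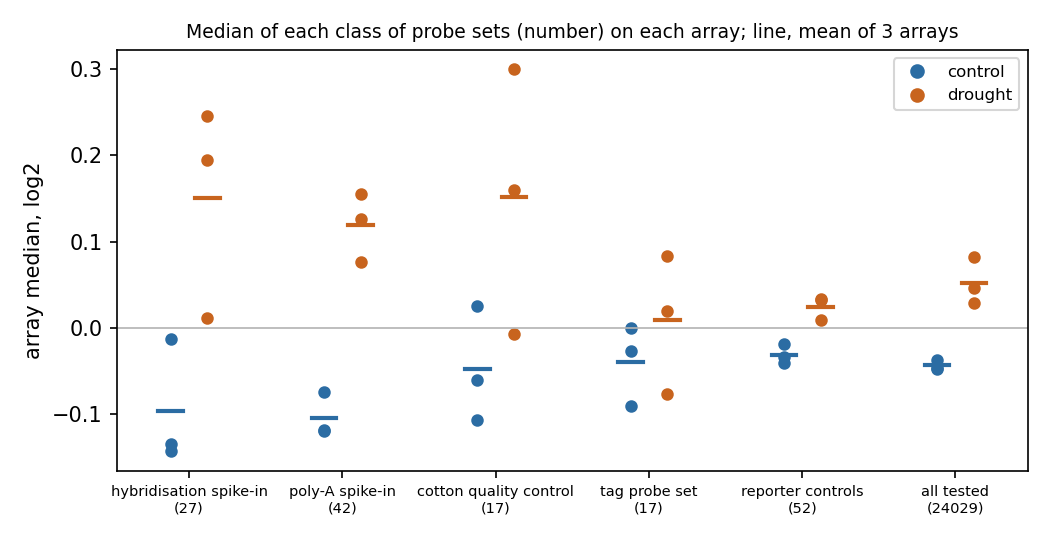
Median log2 signal of each class of probe sets on each array (y axis), with the number of probe sets in brackets; points are single arrays and lines are means of 3 arrays. Hybridisation spike-ins had a mean of 0.151 in drought and -0.0965 in control arrays, and reporter controls 0.0248 and -0.0309.

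Probe sets with no gene name here reached larger differences than any named gene: the 2 largest increases among them were 6.01 (SE 0.10) and 5.92 (SE 0.17), and the 2 largest decreases -9.75 (SE 0.20) and -9.17 (SE 0.11). Of 122 genes with several probe sets, 18 had probe sets that passed in opposite directions and 35 had probe sets over 1 log2 unit apart. XTH1 gave -4.69 on one probe set and -0.53 on the other, EXPA3D gave -2.31 and 0.61, and FatB1 gave 0.30 and -2.87. EXPA1 and susC lie in 1 sequence cluster of the array, 1 of 8 clusters whose probe sets are paired with more than 1 gene, so their values are not shown to be separate measurements, nor to belong to the gene named. The probe set of sad1 lies in another of these clusters, so its value is likewise not shown to belong to that gene. AOX1, FLA4, CesA1, GAI2, vicB_At and LEGB were read from antisense-design probe sets alone, so the strand behind their values is not shown.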

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

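All tests of explanations in this part were chosen after the result was seen. Signals of control probe sets, of which only the reporters were among those tested, differed between the groups: the array median of the hybridisation spike-in probe sets was 0.247 log2 units higher in drought arrays, that of the poly-A spike-ins 0.224 higher, and that of the reporter probe sets 0.0557 higher. In each of these 3 classes all 3 drought arrays lay above all 3 control arrays. Spike-ins are added in fixed amounts and reporter sequences are foreign to cotton, so neither class measures leaf transcripts.

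More probe sets were called higher (8485) than lower (4895), and an offset between arrays in the deposited values may account for this. Whether such an offset was left by the normalization or made by it was not tested. With arrays centred on the reporter array medians, which differed by 0.0557, 57.7% of the calls were still higher. An offset of that size does not remove the excess. The median of the reporters' own log2 differences was larger, 0.0898, and 6 of the 52 still passed after this centring. It therefore takes out less than the reporters' own shift. With arrays centred on the hybridisation spike-ins 35.5% of the calls were higher, so an offset of the size seen in the spike-ins is large enough to turn it. Which of these classes tracks the leaf signal was not tested. RMA scales arrays against one another, so these values cannot decide on a wider rise of leaf transcripts in drought, which stays untested.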

How the results depend on the processing

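Centring on controls, sense-design probe sets alone and the camera background of all probe sets were chosen after the data had been seen. Leaving out 1 array at a time gave 11878 to 13092 changed probe sets, 7409 to 8275 higher, 4465 to 5089 lower, 1554 to 1648 higher and 2055 to 2128 lower at least 2-fold, and 1 preset list and 2 lists from names in each case. Without probe sets that share probes, 12727 were tested and 6673 changed, 4426 higher and 2247 lower, with 920 higher and 989 lower at least 2-fold; 0 preset lists and 0 lists from names passed, with 0 and 7 left to test, and fewer probe sets and genes are the construction of this setting. With treat against a 1.2-fold difference 7856 changed and 4549 were higher, a stricter question by construction. With sense-design probe sets alone 8697 changed and 5235 were higher, of fewer probe sets. With arrays centred on the hybridisation spike-ins 3989 were higher and 1048 were higher at least 2-fold; 11244 changed, of which 8884 were called the same way as in the fit without centring. With all probe sets of the genes 2 preset lists and 7 lists from names passed camera, and with the estimated inter-gene correlation 0 lists from names. With a background of all tested probe sets 8 lists from names passed. Camera adjusted p was then 0.000125 for cell wall enzymes, 0.00015 for the cytoskeleton and 0.00039 for fibre-associated genes. It was 0.000249 for phenylpropanoid and flavonoid enzymes and 0.000704 for fatty acid, wax and sterol enzymes. With an estimated correlation none passed on that background either (lowest camera adjusted p = 0.0804, for FLA). Camera compares a list with its background, and the 2 backgrounds differ. The 324 probe sets with an older gene name had a median log2 difference of -0.04 and an SD of 1.61. Over all tested probe sets these were 0.12 and 1.02, so named genes do not stand for the whole array. How far this accounts for the added lists was not tested. All other alternatives that were run left these counts within 1.5 times of the reported ones. Of the 63 genes picked by the naming rule, only LEGB changed sign, with spike-in centring, and it passed neither before nor after. Among the other genes with an older name that passed, Mn-SOD, GEPH, Di19-2, WD1521, cva69.24, ACO3 and PG changed sign with that centring, and none passed after. Of the values of the 63, 1146 kept their side of the threshold and 4 came to pass, 3 for vicB_At and 1 for LEGB. The labels do not say whether the replicate numbers pair the samples. Same-numbered arrays had deviation correlations of 0.0326, 0.0453 and 0.0741. Each array correlated best with its own number, a hint from the data and not the design. With the replicate block 13244 probe sets changed, 8444 higher and 4800 lower, and 1 preset list and 2 lists from names passed. Filters on dim probe sets, the intensity trend in eBayes and cyclic loess were not run because centred values hold no signal level, which also leaves signal over background unknown.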

Other observations

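The tests of explanations in this part were chosen after the result was seen, except the splits of the arrays; the genes of the next paragraph, which are in none of the lists, were also chosen after their values were seen.

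Several named genes outside the lists differed between droughted and control leaves. MAT gave -2.17, and the cadinene synthase gene cdn1, of the gossypol pathway, gave -1.84; both passed in limma. The phospholipase D gene pldd rose by 1.09, the tocopherol cyclase gene TC by 1.00, and the phosphoenolpyruvate carboxylase gene PEPC1 by 0.60. Ribosomal RNA probe sets gave 0.81, -0.33, 0.46 and -1.43, and all 4 passed.

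Of 2049 array sequences with both a sense and an antisense design, 313 had a sense probe set that passed with at least 2-fold, and for 171 of these the antisense probe set passed in the same direction. Both passed for 633 sequences, in opposite directions for 27. Across these sequences, which are not independent replicates, the log2 differences correlated with r = 0.426.

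Of 36 genes in the fibre-associated, fasciclin-like arabinogalactan protein and cell wall lists, 17 fell at least 2-fold in drought, and RNA of another tissue or of younger, still growing tissue in the control samples is a candidate explanation. A share of other tissue that varied from array to array would spread the control arrays apart. The mean of the 17 genes, however, ranged over only 0.0599 log2 units across the control arrays, against a difference of -3.63 between groups. For the 26 genes that passed and fell by any size the range was 0.0875 and the group difference -2.60. For all 36, taken whatever their change, the range was 0.0487 and the group difference -1.79. These sets of genes overlap, so their ranges are not independent. The same difference in tissue makeup or leaf stage in all 3 arrays of each group cannot be told apart from drought, because it would follow the groups. Of the markers, 5 of 6 fibre-associated genes and the flower genes MADS-1 (-4.21) and SEPALLATA3 (-1.56) fell, which goes with this explanation, while the other 3 flower genes and the seed storage genes did not pass and RCA1, the only photosynthesis gene in the lists, differed by 0.604. An effect of drought on wall and growth genes in the leaf stays open, as untested.

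Large decreases outnumbered large increases, and more degraded RNA in the drought arrays could leave such a skew. It would raise the 3' minus 5' difference of the quality control genes, which was above 0 for 3 of the 6 pairs. On the upland cotton probe sets it fell, with -0.57 for actin, -0.24 for ubiquitin and -1.83 for sucrose synthase, each beyond the SD of either group. On the Gossypium raimondii probe sets actin gave 0.64, while 0.06 for ubiquitin and 0.03 for sucrose synthase lay within the SD of the drought arrays, though 0.06 was beyond that of the control arrays. The 2 largest differences came with changes in signal. Upland cotton sucrose synthase gave -2.12 on the 3' and -0.29 on the 5' probe set, and Gossypium raimondii actin 1.83 and 1.19. A change in transcript level that the 2 ends report unequally would also move these differences, so they need not measure degradation. As actin also gave opposite signs on the 2 designs, more degraded RNA in the drought arrays stays open, and an effect of drought itself is untested.

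There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 13380 changed probe sets and the highest other 0; for at least 2-fold higher the values were 1593 and 0, and for at least 2-fold lower 2074 and 0, so that 1 split, the real one, reached each of these counts. For the preset list the real split gave 1 and the highest other 1, reached by all 10 splits. For the lists from names the real split gave 2 and the highest other 4, and 5 splits reached as many. Every other split sets 2 arrays of one group and 1 of the other against the rest, so it keeps part of the group difference. The rest of that difference enters the spread within each side of the split. Counts of 0 there follow from this spread and do not measure what chance alone would give.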
